A study of Oryza sativa Japonica Group with 18 samples.

How the data were processed

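RNA of dark-grown rice mesocotyls was measured on 18 one-colour Agilent rice arrays, 3 for each of 6 groups: WT, d10-1 and d14-1 (d10 and d14 below), each with and without GR24. The groups and replicate numbers came from the labels. The deposited scanner files give, for each spot, a fluorescence intensity after the scanner software's background subtraction and detrending, with surrogate values near background, and no scaling between arrays. The deposited series table holds the same intensity for every spot, with a largest relative difference of 0 on each array, so using it in place of the scanner files could change nothing and it was not run apart. The mean spot intensity and the local background intensity in the deposited files served for 1 alternative. Other columns of the deposited files are marks of 0 or 1, such as whether a spot was well above background. The submitters' processing notes name Agilent Feature Extraction 10.5.1.1, while the file headers give 9.5.3.1. No unit or group depends on which of them is right.

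Each array held 43734 probe spots, of which 80.6% to 86.1% were well above background. The number of arrays limits the precision of each value. Spots that carry the same probe sequence were averaged without those the scanner software marked as outliers, giving 37896 probes. By the locus numbers in the probe names of the files, 37200 of these map to 1 locus, 428 to none and 268 to several. The 590 control spots of the array's designer were left out. For each array the 75th percentile of log2 intensity was subtracted. Each locus was represented by its probe with the highest mean over all arrays, and probes without a single locus stayed as their own feature, giving 29277 features. The 24415 features that were well above background on all 3 arrays of at least 1 group were tested. Names such as D14, D53 or FC1 were written beside locus numbers by hand with the gene lists, because the deposited files give descriptions only, and they were not checked against a database. The reference table held none of the locus numbers, so no coordinates are given and order along a chromosome is the order of the locus numbers.

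Group means of all 18 arrays were fitted in 1 model with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3. The main fit had no replicate block, which was run as an alternative. Residuals of arrays with equal replicate number correlated above 0.1 in all 3 pairs in some comparisons. These were GR24 in d10 (0.26 to 0.53), GR24 in d14 (0.39 to 0.57), d14 against WT (0.16 to 0.54) and d14 against d10 (0.49 to 0.74). In the other differences between groups, not all pairs did. The 8 differences between groups and the 3 differences of GR24 effects between lines were tested. P values were adjusted by the Benjamini-Hochberg method within each comparison, and features under 0.05 were counted by direction. A fold against a group that was well above background on 0 of its 3 arrays is given as a lower bound, computed against the lowest signal well above background on those arrays. The test was checked on simulated data for d10 against WT, in 5 runs with 200 changed genes among 24372 each. It recovered 52.4% of genes changed by 1 on the log2 scale, 84.4% at 2, 94.8% at 3 and 98.4% at 4, with 0 false calls. These runs reordered the residual arrays, which breaks error common to a slide or replicate. They therefore say nothing of false calls from such error.

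A set of 29 gene lists was fixed by locus number or description wording. They cover strigolactone, cytokinin and other hormone genes, cell division, cell walls, stress and the cytosolic ribosome, and include markers of leaf, seed, root and shoot apex tissue. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists within each comparison. A further 11 lists were written after the wording of the descriptions had been seen, and their p values were adjusted over all 40 lists. Camera with an estimated correlation and fry were run beside it. List members past 0.05 were also counted with p values adjusted over the list alone. Statements on single genes follow a rule fixed in advance. It takes D10 and D14, members of the strigolactone, type-A response regulator and TCP lists that passed, and in 5 comparisons the 5 largest rises and falls. Those had to have an informative description, no overlap between groups and signal well above background in the higher group. It also takes 3 members of each list that passed. Of each difference of GR24 effects it takes the 5 smallest p values among genes with an informative description. Genes outside this rule are marked as chosen after their values were seen.

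The percentage of genes called in d14 against WT that moved the other way with GR24 in d10 shares no array between its parts, and is given with a Clopper-Pearson 95% interval that treats genes as independent, which they are not. Genes called in both mutants were counted, although both comparisons use the same WT arrays. In 100 simulations without group differences, made by reordering the residual arrays, the same counts and the covariance were taken; a count of shared genes is uninformative there, since without differences few genes can be called. Because the control arrays of d10 and d14 shared slides, the residuals of all arrays of a slide were also turned around in sign together, a choice made after seeing the data. Of the 128 sign patterns, the 45 that left error in every group used were kept. The return of called genes was also taken with the lines at their fitted differences and GR24 without effect in d10. Called genes in windows of 100 neighbouring tested genes were compared with 10000 random placements.

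Line identity of each array was checked with markers chosen on the untreated arrays, with the array in question left out: features at which the 3 arrays of a line were separated from those of the other lines by more than 1 on the log2 scale. A gap of 2 was run as well. This check, like every test of the arrays, was chosen after the values were seen. Samples were never regrouped, and both arrays in doubt stayed in the fit under their labels.

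The alternatives were other normalizations (quantile, median, normexp with quantile), other filters, the mean of a gene's probes or every probe apart, a floor on dim values, a trended robust prior, array quality weights, replicate or slide as a block, a fit of only the groups compared, a minimum change of 1, and each array left out in turn. These, the comparisons and the 29 lists were chosen before the data were examined. Leaving out both doubted arrays, the replicate block without them, gene by gene array weights, a random replicate block, and the restriction to genes outside a chromosome 11 stretch were chosen after seeing the data. So were, for the shares and shared genes every setting but the 3 normalizations, the minimum change and the replicate block, for the lists the replicate block and the arrays left out (d10 GR24 1 among them, which was scanned on another day), and the tests of the arrays, of the chromosome stretches, of the return with GR24 and of its need for the receptor. In all, 39 settings were tried. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.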

Results

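Rice seedlings of the cultivar Shiokari were grown in the dark for 4 days, and RNA of the mesocotyl, the stem below the coleoptile that elongates in darkness, was put on arrays. D10 is a carotenoid cleavage dioxygenase of strigolactone synthesis, so the mutant d10-1 (d10 below) lacks the hormone. D14 is the hydrolase that serves as strigolactone receptor, so the mutant d14-1 (d14 below) cannot perceive it. GR24, a synthetic strigolactone analog, was given at 1 uM in the agar, and controls had the solvent alone. Each of the 6 groups had 3 arrays. No treated array shared a slide with a control array of its line. Each GR24 effect may therefore hold a difference between slides. Between 80.6% and 86.1% of the probe spots of an array were well above background, the 75th percentile of intensity ranged from 4660 to 7560 and 0 to 8 spots were saturated. Log2 values below are relative to each array's 75th percentile, with the standard error (SE) of the fit or the SD and n = 3. Where a group was not well above background on all 3 arrays, marked dim below, a log2 difference uses values under the limit of detection. Its size and rank are then not measured, and only folds given as at least are bounds.

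The array d10 GR24 1 stood apart in handling. It was the only array scanned on another day and was alone on its slide. Its spike-in slope was 0.869, against 0.966 or more on the others, and its 75th percentile was the lowest. A difference of scan day therefore moves in part with treated d10, and values without this array, chosen after seeing the data, are given with the list calls that it changes. In comparisons without treated d10, leaving it out acts only through the spread that all groups share. There it is no check of scan day. On the first principal component, the main axis of difference among arrays (31.4% of the variance), this array lay at 83.9. WT controls lay at 1.16, -63.4 and 45.1, and d14 controls at 7.43, -62.6 and -28.2. Arrays of 1 group were thus far apart, and whether list calls follow this axis was not tested.

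At transcripts that set 1 untreated line apart from the others, 16 arrays followed their labels and 2 did not. The array labelled d14 GR24 2 lay nearer d10 at 100% of 18 markers of d10 alone and nearer d14 at 0% of 28 markers of d14 alone, while the other d14 GR24 arrays lay at 0% and 100%. The array labelled d10 GR24 2 lay nearer d10 at 11.1% of the d10 markers and nearer d14 at 3.57% of the d14 markers, while the other d10 GR24 arrays lay nearer d10 at 100%. With a marker gap of 2 in place of 1, the first lay nearer d10 at 100% of 9 markers and the second at 11.1%. Both arrays were on the same slide. Among the untreated d10 and d14 arrays, the lowest value at the markers of the own line was 81.5%, in d10 control 2, and d14 control 3 lay nearer d10 at 33.3% of 27 markers of d10 alone. Both arrays were kept under their labels, and many counts are also given without them, a choice made after seeing the data.

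**Figure D1:**
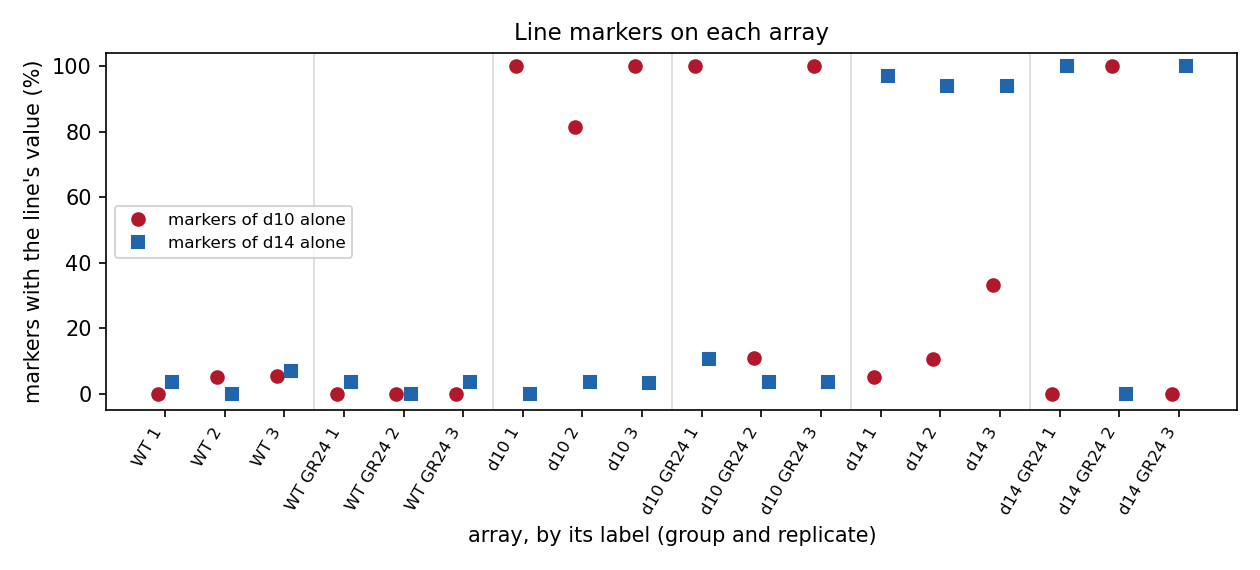
Percent of the markers of d10 alone and of d14 alone at which each of the 18 arrays lay nearer the line in question than the other untreated arrays, with the array itself left out when markers were chosen. The array labelled d14 GR24 2 sits at 100% and 0%, and the array labelled d10 GR24 2 at 11.1% and 3.57%.

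Neither mutated locus had a transcript that passed the test between groups. The D10 transcript (Os01g0746400) was not well above background on any array, with group means from -10.08 to -9.83. D14 (Os03g0203200) was well above background on all arrays, with means of 1.93 ± 0.66 (SD, n = 3) in WT, 2.58 ± 0.37 in d10 and 0.64 ± 0.94 in d14 without GR24. Its difference between d14 and WT was -1.29 (SE 0.62, limma adjusted p = 0.624) and did not pass. With GR24 the means were 1.59 ± 0.41 in WT, 1.80 ± 0.20 in d10 and 0.49 ± 1.54 in d14. The array labelled d14 GR24 2 stood at 2.21, and the other arrays of that group at -0.75 and 0.00. Treated d14 differed from untreated WT by -1.44 (SE 0.62, adjusted p = 0.669), which passed in 5 of 39 alternatives, among them -2.30 (adjusted p = 0.0459) without the array labelled d14 GR24 2.

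Untreated d10 was compared with WT to find what changes when strigolactone is not made. The D53-like gene (Os12g0104300), a close relative of the repressor D53 that strigolactone signalling removes, was lower in d10, at 0.24 ± 0.07 against 1.44 ± 0.32 (SD, n = 3). That is a difference of -1.20 (SE 0.22), 2.30-fold, with adjusted p = 0.0313, which ranged from 1.05e-05 to 0.161 over the alternatives. D53 itself (Os11g0104300) differed by -0.73 and did not pass. Among genes with an informative description, the largest rises, all dim in WT, were a protein kinase (Os11g0694100, 9.5, at least 151-fold), a disease resistance protein (Os11g0639600, 8.62, or 7.11 with a floor under dim values), a DOMON domain protein (Os11g0678200, 7.72, or 6.77), a glycoside hydrolase of family 18 (Os11g0701200, 6.92, or 6.75) and a class III chitinase (Os11g0701000, 6.91, at least 32.4-fold), with SEs from 0.40 to 1.00 and adjusted p from 5.19e-09 to 4.35e-04; Os11g0639600 no longer passed in 2 of 38 alternatives. The largest falls among them, all dim in d10, were a disease resistance protein (Os11g0686500, -6.90, at least 27.6-fold), an importin-beta domain protein (Os11g0693900, -6.80, at least 23.0-fold), a laccase (Os11g0696900, -6.30, at least 22.8-fold) and a pair of resistance proteins (Os11g0676800, -6.22, at least 15.6-fold, and Os11g0673900, -5.85, at least 14.3-fold). All 10 of these lie on chromosome 11, inside a stretch described below that could differ between the seed lines.

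Of the lists, jasmonate and pathogenesis-related genes were higher in d10, with 80 of 115 members higher (camera adjusted p = 7.34e-04, and adjusted p = 0.576 with an estimated correlation). The members that passed were the class III chitinases Os11g0701000 and Os11g0701800 (3.64, SE 0.53). Brassinosteroid genes were higher in 7 of 8 members (adjusted p = 0.0433, and adjusted p = 0.576 with an estimated correlation; 0.0869 with replicate as a block and 0.0605 without d10 GR24 1). Its top members carry the wording of the receptor partner BAK1 (Os06g0225300, 0.89, and Os04g0616700, 0.78). None of them passed over all genes, and 2 passed adjusted over the list alone. In the TCP list, transcription factors that include the tillering repressor FC1, 0 members passed over all genes and 2 fell adjusted over the list alone. FC1 (Os03g0706500) differed by -1.14 (adjusted p = 0.178, dim in both) and OsTCP5 (Os01g0763200) by -1.56 (adjusted p = 0.0854); these were named after their values were seen. The aquaporin PIP2.3 (Os09g0541000) was the member of its list that passed, at 4.14 (SE 0.73, adjusted p = 0.0212), with 1 of 3 WT arrays well above background, so that the size is not measured; it was also named afterwards.

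Over all genes 95 passed, 50 higher and 45 lower (78 by 1 or more; 1849 at an unadjusted p under 0.05), and 10.8% of features did not overlap between the groups, where chance gives 10%. The count was 160 without both doubted arrays and 265 with replicate as a block. It was 53 without WT control 1, 62 without d10 control 2, 57 without d10 control 3 and 149 without the array labelled d14 GR24 2.

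Untreated d14 was compared with WT to find what changes when strigolactone is not perceived. Among genes with an informative description, the largest rises, all dim in WT, were again the kinase Os11g0694100 (9.13, at least 117-fold), the resistance protein Os11g0639600 (8.59, or 7.07 with a floor), the DOMON domain protein Os11g0678200 (8.03, or 7.08) and the chitinase Os11g0701000 (6.65, at least 27-fold). The remaining one was a receptor-domain protein on chromosome 6 (Os06g0581000, 7.56, or 7.24 with a floor, SE 1.32, adjusted p = 0.0191). The largest falls among them were a leucine-rich repeat protein (Os11g0514500, -7.35, SE 1.37, adjusted p = 0.0309) and, dim in d14, Os11g0686500 (-6.90, at least 27.5-fold), the importin-beta domain protein Os11g0693900 (-6.79, at least 22.9-fold), the laccase Os11g0696900 (-6.29, at least 22.7-fold) and the resistance protein Os11g0673900 (-5.65, at least 14.2-fold). All of these but Os06g0581000 and Os11g0514500 lie in the same chromosome 11 stretch. Os06g0581000 lies in a stretch of chromosome 6, described below, that could differ in the d14 line. Os06g0581000 and Os11g0514500 no longer passed in 7 of 38 alternatives each, Os11g0639600 and Os11g0701000 in 2 and Os11g0678200 in 1. The D53-like gene differed by -1.06 (adjusted p = 0.0615) and was the strigolactone gene that passed adjusted over the list alone, with 0 passing over all genes.

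Cytosolic ribosomal protein genes were lower in d14 in 129 of 144 members (median -0.16, adjusted p = 1.06e-05, and adjusted p = 0.865 with an estimated correlation). Examples, none past the test alone, are L30 (Os01g0812800, -0.62), S17-4 (Os03g0109500, -0.45) and L15 (Os06g0308200, -0.24). Over the alternatives they ranged from -0.94 to -0.28, from -0.71 to -0.20 and from -0.29 to -0.11. Markers of root tissue were lower in 7 of 9 members (adjusted p = 0.0247, and adjusted p = 0.237 with an estimated correlation). They include the root-specific RCc2 (Os10g0349300, -2.84, at least 3.22-fold, SE 0.59, adjusted p = 0.0601), RCc3 (Os02g0662000, -0.79) and the silicon transporter Lsi2 (Os03g0107300, -1.87, dim in d14), and 1 member fell adjusted over the list alone. Over the alternatives RCc2 ranged from -3.28 to -0.74, RCc3 from -1.34 to -0.45 and Lsi2 from -2.65 to -0.90. In the cytokinin lists 0 members passed over all genes. Adjusted over the list alone, 1 of 7 metabolism genes rose and 2 fell, and 1 of 4 perception genes fell.

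In all 101 genes passed, 62 higher and 39 lower (84 by 1 or more; 2007 unadjusted), with 10.1% of features not overlapping against 10% by chance. The count was 159 without both doubted arrays and 166 with replicate as a block. It was 52 without WT control 1, 64 without WT control 3, 66 without d14 control 2, 53 without d14 control 3 and 164 without the array labelled d14 GR24 2.

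The mutants changed many of the same genes in the same direction. Of the genes that passed, 66 did so in both, 35 higher and 31 lower, and 0 went opposite ways, while 29 passed in d10 alone and 35 in d14 alone. Transcription factors higher in both included MADS57 (Os02g0731200, 3.61 in d10 and 3.98 in d14) and WRKY60 (Os03g0657400, 3.01 and 3.25), both dim in WT. A cationic peroxidase (Os11g0112200, 2.88 and 2.20), a jacalin-related lectin (Os01g0706800, 1.85 and 1.72) and an S-adenosylmethionine synthetase (Os01g0293000, 0.73 and 0.87) were also higher. A germin (Os09g0568500, -3.24 and -3.19, dim in all 3 lines), a peroxidase (Os07g0677300, -0.85 and -0.79), an annexin (Os09g0453300, -0.87 in each) and a ribosomal protein S6 kinase (Os03g0334000, -0.74 and -0.79) were lower. These 9 were named after their values were seen. Both comparisons use the same WT arrays. Simulations without group differences gave 0 shared genes, but where no gene is changed few can be called. This count therefore does not show how much of the overlap comes from the common WT arrays. The GR24-treated WT arrays enter neither difference. At the 33 shared genes of the chromosome 11 stretch described below, each of them lay nearer WT at 100%. Treated d10 and d14 arrays did so at 0% or 3.03%. These values argue against error of the WT control arrays as the source of the overlap at these 33 genes. For the other shared genes it stays open. The covariance of the 2 differences across genes was 0.178, against an upper 95% limit of 0.155 in the simulations, but 0.140 outside the chromosome 11 stretch described below, and the slide patterns reached 0.232. The covariance is therefore no evidence of sharing beyond the common arrays and slides. The correlation across genes, which are not independent replicates, was 0.786, inside the simulated range of -0.09 to 0.86. The count was 113 with replicate as a block, 89 without both doubted arrays and 42 without WT control 1.

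Many of these genes lie together on chromosome 11. A stretch from Os11g0598800 to Os11g0707700 holds 268 tested genes, of which 35 passed in d10 (16 higher, 19 lower) and 37 in d14 (18 and 19). Among them are the kinase Os11g0694100, the laccase Os11g0696900, the importin-beta domain protein and the chitinases named above. The fullest window of 100 neighbouring genes held 24 genes in d10 and 25 in d14. In a permutation test, random placement gave at most 7 in either, with p = 0.0001, the smallest that 10000 placements can give. Outside the stretch 60 genes passed in d10 (34 higher, 26 lower) and 64 in d14 (44 and 20), 33 of them shared. Without both doubted arrays 124 passed outside in d10 and 80 rose and 43 fell in d14, with 36 inside in each. The stretch was defined after its genes had been seen.

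**Figure D2:**
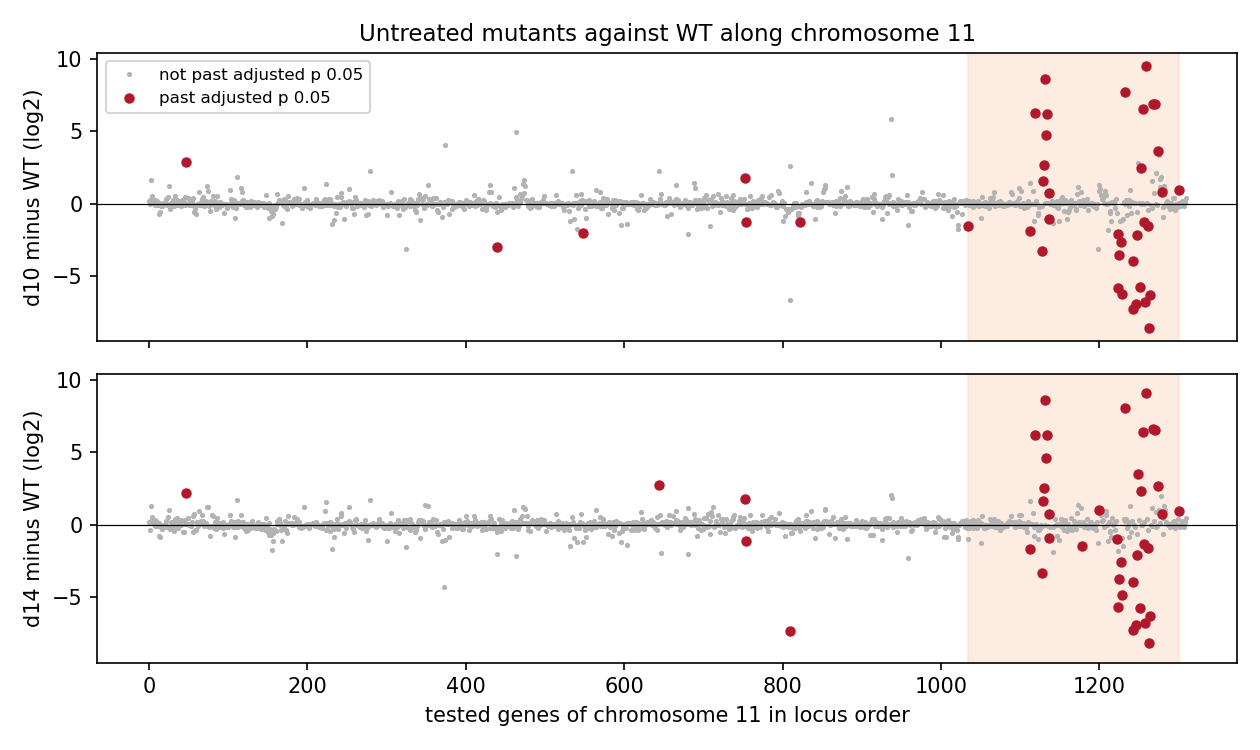
Log2 difference from WT of d10 and of d14 without GR24 (means of 3 arrays) at each tested gene of chromosome 11 in locus order, red where it passed the test. In the shaded stretch of 268 genes, 35 genes passed in d10 and 37 in d14.

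Untreated d14 and d10 were compared to see where loss of perception differs from loss of synthesis. Root tissue markers were lower in d14 in 8 of 9 members (median -0.53, adjusted p = 2.25e-05), and theirs was the list call that held with an estimated correlation (adjusted p = 0.0116), though not with fry (adjusted p = 0.296). The RCc2 genes Os10g0349300, Os10g0551800 and Os10g0552300 differed by -1.77 (dim in d14), -1.12 and -0.71. Ribosomal protein genes were lower in 141 of 144 members (median -0.11, adjusted p = 1.65e-08, and adjusted p = 0.821 with an estimated correlation). Lower in d14 were also peroxidases in 45 of 69 members (adjusted p = 0.00165, and adjusted p = 0.515 with an estimated correlation) and lignin genes in 34 of 54 (adjusted p = 0.00226, and adjusted p = 0.685 with an estimated correlation). The abscisic acid list, mostly dehydrins, was higher in 7 of 8 members (median 0.53, adjusted p = 0.00165, and adjusted p = 0.499 with an estimated correlation). Xyloglucan enzymes (6 of 9 lower), gibberellin genes (7 of 10 lower) and jasmonate and defence genes (68 of 115 lower) each had adjusted p = 0.0416, with adjusted p = 0.515, 0.616 and 0.685 with an estimated correlation. With replicate as a block, the first and the second of these no longer passed (0.0708 and 0.0648), without both doubted arrays the third did not (0.0526), and without d10 GR24 1 the first did not (0.0535).

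No single gene passed in this comparison by limma: 0 over all genes, 338 at an unadjusted p under 0.05, and 5.67% of features without overlap against 10% by chance. The count stayed 0 with replicate as a block. It was 31 without the array labelled d14 GR24 2, 47 without both doubted arrays and 35 when only the groups compared were fitted. At 56 features the untreated arrays of d10 and of d14 were separated by more than 1 on the log2 scale. The array labelled d14 GR24 2 lay nearer d10 at 98.2% of these, and it enters the spread that all groups share. The count of 0 with all arrays therefore does not show that the lines are alike.

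GR24 was given to d10 to see which changes the missing hormone reverses. A formamidase-like gene (Os01g0764900) fell with GR24 from -2.84 to -4.28, a difference of -1.44 (SE 0.19, adjusted p = 0.0462), 2.72-fold. An inhibitor of invertase or pectin methylesterase (Os10g0508700) rose by 1.02 (SE 0.14, adjusted p = 0.0462), 2.03-fold. These calls ended in 25 and 23 of 39 alternatives. The third gene, Os01g0723500, which has no description on the array, rose by 1.42 and was named after its value was seen. In untreated d10 each of the 3 differed from WT in the other direction, by 1.71, -0.75 and -1.90. Those differences use the same d10 control arrays, and simulations without group differences gave 89.8% of d10 genes moving the other way. The D53-like gene (Os12g0104300) differed by 1.03 with GR24 in d10 (adjusted p = 0.220) and by 0.09 in d14 (-0.20 without the array labelled d14 GR24 2), reaching 1.27 ± 0.07 (SD, n = 3) in treated d10, and the difference between these effects, -0.94 (SE 0.32), did not pass. FC1 and OsTCP5 differed by 1.35 and 0.99. Of the TCP list 2 members, and of the strigolactone list 1, rose adjusted over the list alone, with 0 over all genes.

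Jasmonate and defence genes were lower with GR24 in d10 in 84 of 115 members (median -0.32, adjusted p = 0.00241, and adjusted p = 0.953 with an estimated correlation). Examples are the pathogenesis-related factors Os01g0200600 (-0.95) and Os05g0549800 (-0.72). None of the 3 list calls in this comparison held without d10 GR24 1: the adjusted p was then 0.0989 for these genes, 0.523 for lignin and 0.138 for ribosomal protein genes. Lignin genes were lower in 44 of 54 (adjusted p = 0.00869, and adjusted p = 0.953 with an estimated correlation), among them cinnamoyl-CoA reductases (Os01g0283600, -1.10, and Os06g0623600, -0.63) and a laccase (Os12g0257800, -0.92). The last pair rested largely on d10 GR24 1, with -0.33 and -0.27 without it. Without both doubted arrays lignin no longer passed (0.122). Ribosomal protein genes were higher in 115 of 144 (adjusted p = 0.00363, and adjusted p = 0.953 with an estimated correlation).

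By limma 3 genes passed, 2 higher and 1 lower (2201 unadjusted), and 14.7% of features did not overlap, against 10% by chance. The count was 17 with replicate as a block and 7 without both doubted arrays. It was 17 without the array labelled d14 GR24 2, 1 without d10 GR24 3, and 0 without any of the 3 WT control arrays, the 3 WT GR24 arrays, the 3 d10 control arrays, d10 GR24 1, d14 GR24 3, or d14 control 2 or 3.

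**Figure D3:**
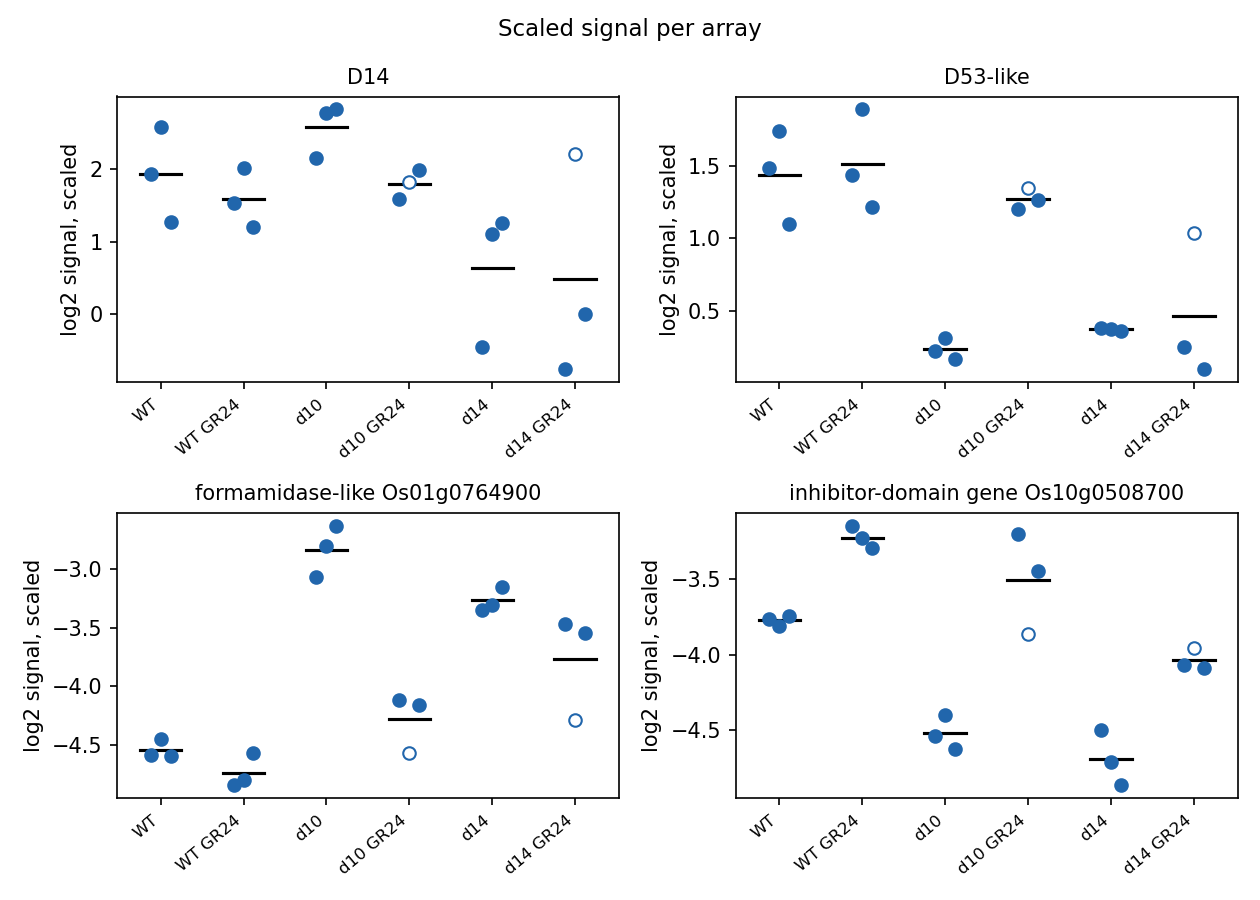
Log2 signal relative to the 75th percentile of D14, the D53-like gene, the formamidase-like gene Os01g0764900 and the inhibitor gene Os10g0508700 on each array; bars are means of 3 arrays and open circles the arrays that go against their labels. The D53-like mean is 0.24 in d10 and 1.27 in d10 with GR24, and 0.37 and 0.46 in d14.

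Genes changed in the d14 mutant were followed in GR24-treated d10, a comparison that shares no array with the first. Of the 101 genes, 78 moved the other way with GR24 in d10, 77.2% (95% Clopper-Pearson interval 67.8 to 85). Outside the chromosome 11 stretch the share was 82.8% (53 of 64), with the cationic peroxidase Os11g0112200 at -2.64 and, both dim, the germin Os09g0568500 at 1.88 and WRKY60 (Os03g0657400) at -1.47 (-0.90 without both doubted arrays). MADS57 (Os02g0731200) stayed near its mutant level, at -0.17. The converse, d10 genes followed in GR24-treated d14, gave 57 of 95, 60% (49.4 to 69.9). The median of the difference that GR24 took back was 12.5% in the first case and 2.69% in the second. Without the array labelled d14 GR24 2 they were 19.1% and -4.18%, and without both doubted arrays 22.5% and -3.58%. The d10 and d14 control arrays shared 3 slides, so their error may be common. With no group differences and the error of whole slides turned around together, the first share was 65.3% on average (49.6 to 88.7) and 64.4% outside the stretch (45.6 to 85.8). The observed shares lie within these ranges and so are not shown to exceed what common error of the slides gives where no line differs. The shares were not simulated with the lines at their fitted differences. With those differences kept and GR24 without effect in d10, the median taken back outside the stretch was at most 17.2%, against 32.5% observed. With no group differences its upper 95% limit was 41.1%. The share in d10 was 75.5% without both doubted arrays, 81.9% with replicate as a block and 63.2% with slide as a fixed block. The share in d14 was 41.2% without both doubted arrays and 40.9% without the array labelled d14 GR24 2, on the other side of 50%. The share of d10 genes that moved the other way in d10 itself, 85.3%, uses the d10 control arrays on each side, and was not above the 89.8% (40.9 to 100) of simulations that reorder the residual arrays.

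**Figure D4:**
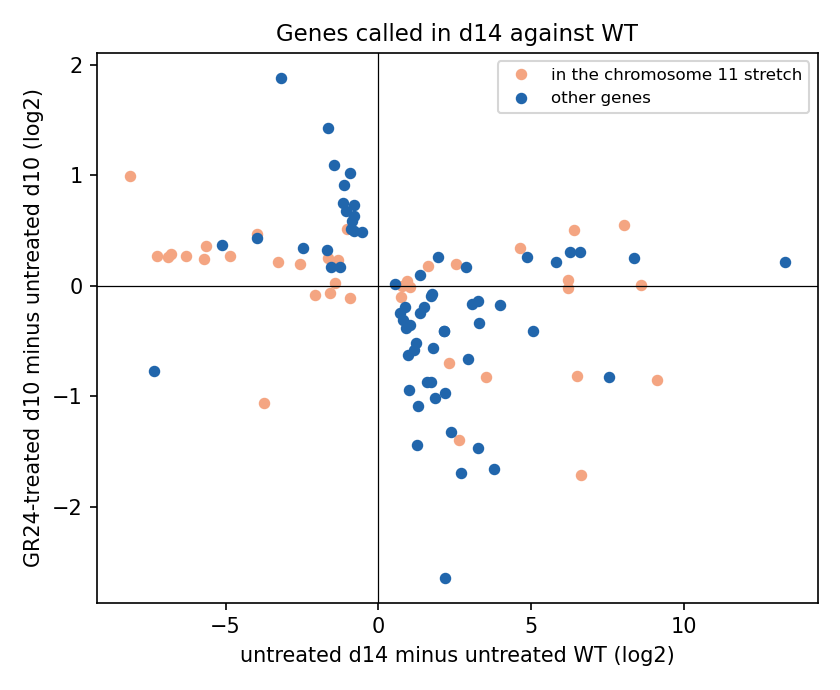
Difference of d14 from WT (log2, without GR24) against the GR24 effect in d10 (log2) for the 101 genes that passed in d14 against WT, inside and outside the chromosome 11 stretch. Of these, 78 lie in the quadrants of opposite sign.

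GR24 was given to WT to see what added strigolactone changes when synthesis and perception are intact. Ribosomal protein genes were higher in 137 of 144 members (median 0.18, adjusted p = 2.42e-11), core histones in 41 of 44 (0.00128), peroxidases in 47 of 69 (0.0103) and TCP factors in 7 of 7 (median 0.44, 0.0293). The abscisic acid list was lower in 7 of 8 members (median -0.66, adjusted p = 0.0103), including the dehydrins Os11g0454200 (-1.35, SE 0.66) and Os11g0454300 (-1.41, SE 0.60). Each of these 5 lists had adjusted p = 0.999 with an estimated correlation. Treated and control WT arrays were on different slides. Whether these list calls follow slide or the main axis of difference among arrays was not tested. No single gene passed by limma, with 0 over all genes, 214 at an unadjusted p under 0.05 and 2.99% of features without overlap against 10% by chance. The count was 0 as well with each array left out and with replicate as a block, but 14414 and 5388 with the array quality weights. Those counts rest largely on 1 array of each WT group. The default weights were 81.8 for WT control 1 and 11.9 for WT GR24 1, against 0.21 to 0.34 for the other WT arrays.

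GR24 was given to d14 as the control that lacks the receptor. Treated and control d14 arrays were on different slides. Whether the list calls below follow slide or the main axis of difference among arrays was not tested either. Ribosomal protein genes were again higher, in 140 of 144 members (median 0.20, adjusted p = 1.73e-10), as were peroxidases in 45 of 69 (0.003, including Os04g0688200, 0.75). Lignin genes were higher in 38 of 54 (0.0424), among them the laccases Os03g0273200 (1.13) and Os11g0108700 (0.52). Over the alternatives these laccases ranged from 0.66 to 2.13 and from 0.37 to 0.96. These 3 lists had adjusted p = 0.856 with an estimated correlation, and lignin no longer passed without both doubted arrays (0.108), without d10 GR24 1 (0.0530) or with replicate as a block (0.0604). By limma 0 genes passed (736 unadjusted; 13.0% of features without overlap against 10% by chance), and 0 passed without either doubted array or with replicate as a block.

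Treated mutants were also set against untreated WT, to see what GR24 leaves. In treated d10 the DNA replication genes were higher in all 19 members (median 0.29, adjusted p = 0.0208, and adjusted p = 0.917 with an estimated correlation), among them the origin recognition genes Os06g0187000 (0.73) and Os03g0184700 (0.17). This call ended without both doubted arrays (0.0687) and without d10 GR24 1 (0.601). Over the alternatives Os06g0187000 ranged from 0.21 to 1.14 and Os03g0184700 from 0.030 to 0.27. In treated d14 strigolactone genes were lower in 7 of 8 members (median -0.44, adjusted p = 0.0234, and adjusted p = 0.602 with an estimated correlation), with 0 past the test over all genes and 1 adjusted over the list alone. Jasmonate and defence genes were higher in 79 of 115 (adjusted p = 0.0234, and adjusted p = 0.841 with an estimated correlation), with the chitinases Os11g0701000 (6.40, at least 22.6-fold) and Os11g0701800 (2.90) past the test, the latter lost in 17 of 39 alternatives and the former in 1 of 38. Over all genes 50 passed in treated d10 (22 higher, 28 lower; 1163 unadjusted; 36 on chromosome 11) and 60 in treated d14 (34 and 26; 1699 unadjusted; 36 on chromosome 11). Of these, 33 in treated d10 and 34 in treated d14 lay in the chromosome 11 stretch. Without both doubted arrays the counts over all genes were 78 and 213, with slide as a fixed block 13 and 134, and with replicate as a block 67 and 206. Without the array labelled d14 GR24 2 alone the second was 215.

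The differences of GR24 effects between lines test whether the response depends on the genotype. The genes with the smallest p values were the aquaporin PIP2.3 (Os09g0541000), whose GR24 effect in d10 minus that in WT was -3.53 (SE 1.03, dim in WT and in treated d10), and the formamidase-like Os01g0764900 at -1.25 (SE 0.27). A cytochrome P450 (Os06g0671300, -3.19, dim), a bHLH factor (Os01g0952800, 1.86, dim) and an aldo/keto reductase (Os04g0337700, -0.98) were next in that comparison. For d14 minus WT they were a NAM domain protein (Os01g0393100, -3.49, but -0.81 with a floor), a leucine-rich repeat protein (Os10g0469000, 1.76), a BURP domain protein (Os10g0409400, -1.77), a transferase (Os02g0486500, 0.94) and Os05g0410500 (0.68). The NAM domain gene was dim in WT and in treated d14. For d14 minus d10 they were PIP2.3 (3.74, SE 1.03, dim), the cationic peroxidase Os11g0112200 (2.26), Os10g0469000 (2.0), a xyloglucan enzyme (Os04g0604300, 1.39) and a proline-rich protein (Os06g0168700, -1.05). None passed by limma, with 0 genes in each comparison and 284, 88 and 499 at an unadjusted p under 0.05. Of the lists, lignin genes were higher in d14 minus d10 in 44 of 54 members (adjusted p = 4.25e-07, and adjusted p = 0.373 with an estimated correlation), led by phenylalanine ammonia-lyases (Os02g0626600, 2.12, and Os04g0518400, 1.32). Jasmonate and defence genes were higher in 83 of 115 (adjusted p = 5.28e-05, and adjusted p = 0.373 with an estimated correlation), led by a thaumatin-like protein (Os12g0629600, 1.1, dim). Without d10 GR24 1 the adjusted p was 0.0132 for each of these lists. So no single gene's GR24 effect was shown to differ between lines.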

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

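Of the tests in this part, those of the lists were planned, the second probes of a gene and the slide block on the share were added after seeing the data but before their results were seen, and the others were chosen only after.

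In 8 cases a gene list responded to GR24 differently in 2 lines, by camera on the difference of effects. Gibberellin genes were lower in d10 minus WT in 10 of 10 members (adjusted p = 0.0253, and adjusted p = 0.922 with an estimated correlation; 0.112 without both doubted arrays). Jasmonate and defence genes were lower in d10 minus WT in 85 of 115 (adjusted p = 0.00148, and adjusted p = 0.922 with an estimated correlation). Lignin genes were higher in d14 minus WT in 46 of 54 (adjusted p = 8.52e-06, and adjusted p = 0.739 with an estimated correlation). The abscisic acid list was higher in d14 minus WT in 7 of 8 (adjusted p = 0.00318, and adjusted p = 0.739 with an estimated correlation; 0.049 with it and without both doubted arrays). In d14 minus d10, lignin genes were higher in 44 of 54 (adjusted p = 4.25e-07) and jasmonate and defence genes in 83 of 115 (adjusted p = 5.28e-05), each with adjusted p = 0.373 with an estimated correlation. Gibberellin genes were higher in d14 minus d10 in 8 of 10 (adjusted p = 0.0136) and brassinosteroid genes in 6 of 8 (adjusted p = 0.0165), with the same adjusted p = 0.373 with an estimated correlation. Without d10 GR24 1, the array scanned on another day, both calls in d10 minus WT ended (0.233 and 0.192), as did gibberellin and brassinosteroid genes in d14 minus d10 (0.0808 each), so a difference of scan day is not excluded for these 4. Lignin and jasmonate genes in d14 minus d10 held (0.0132 each), and the calls in d14 minus WT hold no d10 array, so that this says nothing of them.

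The array labelled d14 GR24 2 lay nearer d10 than d14 at 98.2% of the markers that separate these lines, which is consistent with a wrong label on d10 RNA. The second part of that test, that other GR24 arrays follow their labels at 90% or more, was not met, since d10 GR24 1 stood at 89.3% and the array labelled d10 GR24 2 at 66.1%. A mixture of d14 and d10 RNA was argued against by 10 transcripts high in d14 and dim in d10. All were at background on this array, with a median signal of 1.58% of the other d14 GR24 arrays. At the limit of detection the median was at most 7.38%, under the 10% set for a mixture. The bounds of single transcripts ran from 0.036% at Os06g0580100 and 1.27% at Os06g0582300 to 17.9% at Os06g0582400. A share of d14 RNA under these bounds stays open. A pull of the slide toward d10 was argued against by the d14 arrays on other slides with d10 arrays, of which the lowest lay nearer d14 at 93.9% of the markers of d14 alone; on the markers first written down (at most 10% nearer d10) they stood at 10.3%, 9.2% and 30.6%, so this rests on markers chosen later. At the markers of 1 line alone, the array labelled d14 GR24 2 lay nearer d14 at 0% of 28 and nearer d10 at 100% of 18. These values argue against RNA of the d14 line, as labelled, as the main content of this array. How a wrong label arose was not tested, and no biological explanation was tested for a single array.

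The chromosome 11 stretch could be a stretch of the seed lines that differs between WT and both mutants. GR24 took back a median of 4.17% of the difference in d10 inside it (95% interval 0.331 to 7.64), against 32.5% outside (13.6 to 49.6). This argues against a response to the loss of strigolactone that GR24 takes back in the stretch as it does elsewhere. Large differences inside are against dim groups, which lowers the percentage taken back there. Os11g0694100, for example, differed by 9.13 in d14, or by 6.87 with a floor. The return was not computed with a floor, and its intervals treat neighbouring genes as independent. Were GR24 without effect in d10, error common to the arrays of a slide would give a gap between outside and inside of at most 16.5 percentage points, against 28.4 observed. Outside alone it would give at most 17.2%, against 32.5% observed. With no group differences at all it gave -2.24% to 41.1% outside, and a response that GR24 does not take back stays open. Probes hit by single base variants stay open for most genes: of the 4 genes with another probe, that probe moved the same way by 1 or more in 75% (19.4 to 99.4). At the remaining gene, Os11g0689100, the probes went opposite ways, with 2.47 and -2.92 in d10 and 2.31 and -2.97 in d14. Parent lines were not on the arrays, so the descent of the stretch was not tested.

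Movement of d14 genes the other way with GR24 in d10 may be a response that needs the D14 receptor, or error common to slides. The share outside the stretch, 82.8%, lay within the 45.6% to 85.8% that common error of the slides gave with no group differences, so the share alone does not tell them apart. Genes called in the mean of both mutants returned more with GR24 in d10 than in d14 by limma's fry on the difference of effects, with an unadjusted p value of 0.00292 (0.0273 with slide as a fixed block, 1.49e-04 without both doubted arrays and 0.00314 without d10 GR24 1). Outside the stretch the mean signed difference was 0.68, against at most 0.24 in the 45 slide patterns. A shift shared by all GR24 arrays cancels in this difference and so did not produce it. The difference cannot test whether such a shift adds to the movement in d10 alone. The medians, 2.69% for d10 genes in treated d14 against 12.5%, do not settle that. A difference between the slides of treated and control arrays cannot be told apart from a response that needs the receptor. With slide as a fixed block, the share outside the stretch was 53.8%, between the bounds of 50% and 75% set beforehand. Treated and control arrays of d10 were never on the same slide, nor were those of WT or of d14.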

How the results depend on the processing

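Of the tests here, leaving out both doubted arrays, the replicate block with arrays left out, the random replicate block, gene by gene weights, the limits to genes outside the stretch and, for the shares and shared genes every setting but the 3 normalizations, the minimum change and the replicate block, were chosen only after seeing the data. Over the 39 settings, values for named genes kept direction and side of the threshold 5398 times, gained the threshold 65 times, lost it 96 times and turned in sign 23 times, none of them called. List calls were kept 209 times and lost 97 times. For counts and shares, 469 values were the same (counts within 1.5 times), 119 moved and 9 shares crossed 50%. Log2 differences against groups not well above background use values under the limit of detection and are not bounds; only the folds given as at least are. Except where an alternative tests fewer features or arrays by its own construction, the cause was not tested. Using the deposited series table in place of the scanner values was not run, because the values are identical.

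The count for GR24 in d10 (3) was 0 with quantile or median normalization, without a filter, with the mean of probes, with every probe, with a trended robust prior, with slide as a fixed block or with only the groups compared, and 6 with a floor. Array quality weights, whose default method gave a convergence warning, called 14414 for GR24 in WT, 27 in d10, 1 in d14, 9363 for d10 against WT, 8884 for d14 against WT, 1127 and 8028 for the treated mutants, 744 and 279 for d10 minus WT and d14 minus WT, and 6661 shared genes. The gene by gene method called 5388, 20, 1, 5723, 5513, 151 and 4158, then 1 for d14 minus WT, and 3627 shared. The default weights were 81.8 for WT control 1 and 11.9 for WT GR24 1, and those of the gene by gene method 8.12 and 6.45. The other WT arrays had 0.21 to 0.49 by these methods. Weighted counts that involve WT thus rest largely on 1 array of a WT group.

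With replicate as a block the counts were 17 for GR24 in d10, 265 for d10 and 166 for d14 against WT, 206 for treated d14 and 113 shared; 92.8% of d10 genes moved the other way in d10, and 43.0% in d14. As a random block it gave 24, 210, 184, 120 and 115. Slide as a random block gave 215, 201, 94 for treated d14 and 119 shared. Slide as a fixed block gave 13 and 134 for the treated mutants, a share of d14 genes in d10 of 63.2% (53.8% outside the stretch) and of d10 genes in d14 of 44.7% (44.9% outside). With only the groups compared, d14 against WT was 55, d14 against d10 35 and the treated mutants 27 and 31. With signal well above background on all 18 arrays the counts were 44 and 35 for the mutants, 17 and 18 for the treated mutants and 27 shared. With normexp 48.6% of d10 genes moved the other way in d14 and 73.0% in d10. Outside the stretch there were 33 shared genes, and 98.3% of d10 genes moved the other way in d10.

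Without both doubted arrays the counts were 7 for GR24 in d10, 160 and 159 for the mutants, 47 for d14 against d10, and 78 and 213 for the treated mutants, and 41.2% of d10 genes moved the other way in d14. With the replicate block as well they were 33, 330, 262, 57, 92 and 336, with 155 shared and 38.5%. With that block and without d14 GR24 2 they were 52, 329, 248, 37 and 343 (treated d14), with 155 shared, 39.2% in d14 and 92.7% in d10. With it and without d10 GR24 2 they were 11, 268, 161, 80 and 165, 1 for d14 minus d10, 113 shared and 44%. Of the 34 list calls, 1 held with an estimated correlation and 0 with fry, and 11 ended without d10 GR24 1. Some of the latter are in comparisons that hold no treated d10 array, and say nothing of scan day. Without that array 0 of the 3 calls for GR24 in d10 held.

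Leaving out each array in turn gave 0 to 17 for GR24 in d10, 53 to 149 for d10 against WT, 52 to 164 for d14 against WT, 0 to 31 for d14 against d10, 36 to 61 and 42 to 215 for the treated mutants, 42 to 89 shared, 72.0% to 81.1% for the share of d14 genes in d10, 40.9% to 71.6% for d10 genes in d14, 73.7% to 89.8% for d10 genes in d10, and 0 for every other count. The lowest counts of d10 against WT, d14 against WT and shared genes came without WT control 1 (53, 52 and 42). Further low counts were 62 and 57 for d10 without d10 control 2 and 3, and 64, 66 and 53 for d14 without WT control 3, d14 control 2 and d14 control 3. The high ends of d10, d14, d14 against d10, GR24 in d10 and treated d14 came without the array labelled d14 GR24 2, and GR24 in d10 was 0 without most arrays of WT, d10 or d14.

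The turns in sign fell on 7 results for named genes. For D14 (Os03g0203200) they were in 4 comparisons. Its GR24 effect in d14 (-0.15) was -1.01 without d14 GR24 2. It turned positive in 4 of 39 alternatives, reaching 0.46 without d14 GR24 1. Treated d10 against WT (-0.13) was -0.46 without WT control 3, 0.20 without WT control 2, and with the replicate block 0.0751 without both doubted arrays and 0.20 without d10 GR24 2. The effect in d14 minus WT (0.19) turned negative in 9 of 39 alternatives. Among these it was -0.15 and -0.13 with the array weights and -0.67 without both doubted arrays or d14 GR24 2 alone. With the replicate block as well it was -0.45 and -0.50. Without d14 GR24 1 it was 0.81. The effect in d14 minus d10 (0.63) was -0.22 without both doubted arrays, with or without the block, -0.0573 with the block and -0.23 without it when d14 GR24 2 was left out, and 1.24 without d14 GR24 1. Os06g0568600 in d14 against d10 was 0.74 with the mean of probes, Os06g0570100 in d10 minus WT 0.0682 with slide as a fixed block, and Os11g0155900 with GR24 in WT -0.0334 without WT control 2 and 0.92 without WT control 3.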

Other observations

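In this part the splits of the arrays were planned before their results were seen, and the tests of the array labels and of the chromosome 6 stretch were chosen only after.

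Beside the D14 gene itself, 2 neighbouring loci were higher in untreated d14 and not called in d10: Os03g0203300, which has no description (3.78, SE 0.63, adjusted p = 0.0137, dim in WT), and a plasma membrane calcium ATPase (Os03g0203700, 1.96, SE 0.32, adjusted p = 0.0103). Other genes called in d14 alone were the precursor of the growth peptide phytosulfokine (Os12g0147800, 0.98, SE 0.20, adjusted p = 0.0486) and a peroxiredoxin (Os07g0638300, 1.72, SE 0.35, adjusted p = 0.049). Genes called in d10 alone were a cation transporter (Os02g0175000, -3.17, SE 0.62, dim in d10) and a phototropism-related NPH3 domain protein (Os04g0477000, 1.36, SE 0.26). All were chosen after their values were seen, and none was shown to differ between the mutants.

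Lists written after the wording of the array was seen, adjusted over all 40, gave further groups. Expansins, wall-loosening proteins of elongation, were lower in d14 than in WT in 27 of 42 members (adjusted p = 0.0239, and adjusted p = 0.499 with an estimated correlation) and lower than in d10 in 31 of 42 (adjusted p = 2.22e-04, and adjusted p = 0.113 with an estimated correlation). They were higher with GR24 in d14 in 28 of 42 (adjusted p = 0.0405, and adjusted p = 0.700 with an estimated correlation). Cellulose synthases were lower in d14 than in WT in 17 of 22 (adjusted p = 0.0239, and adjusted p = 0.499 with an estimated correlation), and their GR24 effect was higher in d14 minus WT in 18 of 22 (adjusted p = 0.0106, and adjusted p = 0.681 with an estimated correlation). Tubulins were lower in d14 than in WT in 11 of 12 (adjusted p = 0.0131, and adjusted p = 0.499 with an estimated correlation) and than in d10 in 10 of 12 (adjusted p = 0.0170, and adjusted p = 0.698 with an estimated correlation). The wider replication list was higher with GR24 in WT in 21 of 25 (adjusted p = 0.0499), in d14 in 23 of 25 (adjusted p = 0.0405) and in treated d10 against WT in 24 of 25 (adjusted p = 0.00752), and these had adjusted p = 0.999, 0.862 and 0.868 with an estimated correlation; the last was 0.486 without d10 GR24 1. Root tissue markers were also lower in d14, in 7 of 9 members against WT (adjusted p = 0.0247, and adjusted p = 0.237 with an estimated correlation) and 8 of 9 against d10 (adjusted p = 2.25e-05, and adjusted p = 0.0116 with an estimated correlation), so a different share of root tissue could lie behind the falls of these wall and tubulin lists. Kinesins were higher with GR24 in d10 in 37 of 44 (adjusted p = 0.0293, adjusted p = 0.934 with an estimated correlation and 0.688 without d10 GR24 1), and cytokinin perception genes lower in treated d14 in 12 of 12 (adjusted p = 0.0283, and adjusted p = 0.774 with an estimated correlation).

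The remaining lists passed in no comparison. Their smallest adjusted p were 0.0697 for type-A response regulators (8 measured), 0.134 and 0.613 for cytokinin perception and metabolism, 0.405 for karrikin genes, 0.382 for mitosis, 0.405 for D-type cyclins, 0.176 for the narrow expansin list, 0.535 for the narrow cellulose synthase list and 0.222 for aquaporins. They were 0.238 for auxin response, 0.436 for ethylene, 0.0816 for heat shock and 0.0681 for light signalling. Markers of other tissues gave 0.0913 for leaf, 0.280 for seed and 0.429 for shoot apex. Among the lists added later they were 0.0979 for cyclins, 0.10 for auxin response, 0.128 for aquaporins, 0.0524 for TCP factors and 0.436 for KNOX genes. For heat shock, 0 members passed over all genes and 4 of 105 rose in d14 against WT adjusted over the list alone.

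The array labelled d10 GR24 2 may carry RNA of another source. It lay nearer WT at 0% of the 33 shared genes of the chromosome 11 stretch, which argues against the WT line, and nearer d14 at 3.57% of the markers of d14 alone, which argues against the d14 line. A loss of d10 values with GR24 was argued against by the other d10 GR24 arrays, which each lay nearer d10 at 100% of those markers. A swap between this array and the one labelled d14 GR24 2 was argued against by the markers of d14 alone, where arrays labelled d10 GR24 reached at most 10.7%; the bound first written (10% on the markers of both lines) was not met, with 33.9%, so this rests on a bound set later. Both arrays as the same RNA hybridised again was argued against by 16 of 18 markers of d10 alone at which they lay on opposite sides, although they differed by over 1 at 313 features against 592 in the closest untreated pair, as that explanation had been written to need. What this array carries stays open.

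A stretch of chromosome 6 from Os06g0558900 to Os06g0583500 could differ in the d14 line. Without the array labelled d14 GR24 2, d14 against d10 called 31 features, and a window of 100 genes there held 12 of them, against a highest value of 5 in random placements (permutation p = 0.0001, the smallest that 10000 placements can give). With all arrays, 8 of the 17 tested genes from Os06g0574700 to Os06g0583500 passed in d14 against WT, among them Os06g0581000, and they lie within it. The descent of the stretch was not tested.

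Splits of the same arrays into other groups were counted for each comparison. With 3 arrays against 3 there are 10 splits, so that no share under 0.1 is possible. The real split called 95 in d10 against WT (highest other 1), 101 in d14 against WT (0), 50 in treated d10 (0), 60 in treated d14 (1) and 3 for GR24 in d10 (0), and 1 split reached the real count in each. For d14 against d10 and GR24 in d14 all 10 splits called 0, which says nothing. For GR24 in WT 10 of 10 reached the real 0, and the split of WT control 1, WT control 2 and WT GR24 2 against the rest called 4094, a structure that does not follow treatment; these 6 arrays were on 6 slides, so slide cannot be told from array. For the share of d14 genes in d10, 77.2%, 2 of 10 splits lay as far from 50%, the other with 80.2% moving the opposite way to the real split. For the differences of GR24 effects all 100 drawn splits reached the real 0, with highest others of 1021 for d10 minus WT, 4731 for d14 minus WT and 23 for d14 minus d10. Where the real count is 0 every split reaches it, so these splits say nothing about chance.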
